A study of Mus musculus with 4 samples.

How the data were processed

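The series holds total RNA from the CA1 field of the hippocampus of young male C57BL/6J mice that were handled and received no other treatment, measured on 4 single-channel expression arrays. Per the labels, the arrays differ in the hour of RNA extraction, 1, 2, 4 or 6 hr after a separate set of shocked mice had received the last shock. Each time has 1 array. How many mice went into an array is not given in the sources used here. Arrays of shocked mice were not analysed here.

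The authors deposited 1 intensity per probe set and array, for 12488 probe sets of a mouse oligonucleotide array. How the probe-level data were summarised, and with what software, is not given in the sources used here. The deposited intensity values are linear, are all above 0, and have 1 decimal. The mean of each array's values after trimming 2% at each end was 500.3, so the arrays had been scaled to a common level before deposit, a reading from the values and not from a label. Scaling of this kind sets the overall level of each array equal, so a change shared by most genes cannot be seen. No detection calls were used here, so whether a dim probe was above background is unknown. The number of arrays limits the precision.

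Probe sets were named from the platform's annotation table: 10855 had 1 gene symbol, 396 had several and 1237 had none. Of the probe sets with 1 symbol, 10839 matched a mouse RefSeq gene (assembly GRCm38.p6) through the Entrez identifier, and no symbol differed. The 66 control probe sets were left out of tests and used to describe the arrays. Genomic coordinates were not used here.

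The deposited scale was kept. Values under 54.7, the 25th percentile of all values, were set to that floor and log2 values were taken. The 7453 probe sets with a mean log2 value above the 40th percentile were tested, and 6710 of them had 1 symbol, for 5680 genes. Fold changes are on this floored scale, so a fold that involves a value at the floor is written as at least that size. Values on the floor have no order among themselves.

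A straight line over the hours was fitted to each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 2 residual degrees of freedom, and two-sided p-values were adjusted with the Benjamini-Hochberg method at 0.05. No pair of times can be tested with 1 array each. A probe set was counted as standing apart on an array when it lay at least 1 log2 unit (2-fold) above, or below, each of the other 3 arrays, with no p-value. No source used here says that the arrays come from separate animals, so the p-values measure only the spread between these arrays around a line, which may be technical.

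Before the data were examined, 24 gene lists were fixed: 12 pathway lists (immediate early genes, glucocorticoid responsive genes, circadian clock genes, heat shock and chaperone genes, NF-kB pathway genes, ionotropic glutamate receptors, GABA-A receptors, synaptic vesicle genes, chromatin deacetylases and acetyltransferases, ribosomal proteins, oxidative phosphorylation, proteasome) and 12 marker lists (CA1 and CA3 pyramidal neurons, dentate granule neurons, inhibitory neurons, astrocytes, oligodendrocytes, microglia, endothelial and mural cells, choroid plexus and ependyma, blood, striatum, thalamus). Each gene entered with its probe set of highest mean. The slope of each list was tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists. The estimated form rests on the 2 residual degrees of freedom, so it can hardly pass any list. A list that fails it is not thereby argued against. On each array, a list's median difference from the mean of the other 3 arrays was placed among 10000 random lists of the same size matched on mean level; these percentiles describe the arrays and are not p-values.

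The rule for the genes named was fixed at the same time. They are the 10 rising and 10 falling genes past the threshold, filled where fewer passed with those of smallest unadjusted p whose 4 values were in strict order of time; the 5 genes farthest above and the 5 farthest below on each array; and in each list the 2 members with the largest positive and the 2 with the largest negative difference of 4 and 6 hr from 1 and 2 hr. Only probe sets with 1 symbol were named. An SD with n = 4 is taken over the 4 arrays, 1 at each time, and not over replicates.

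The trend test was tested on simulated data. The variance of each probe set was drawn from the prior that limma fitted to these arrays, whatever its mean level. With 200 of 7453 probe sets changed, the trend test recovered 89.1% of slopes of 0.8 log2 units per hr and 0% of slopes of 0.4 (a 4-fold change over 5 hr). The alternatives tried were quantile normalization, a shift to a common median, floors at the 10th and 40th percentile, no filter and a filter at the 60th percentile, each array left out, log2 of hours, 4 and 6 hr against 1 and 2 hr, other variance models, 1 probe set per gene or all of them, and a 1.5-fold size rule. Figures were drawn with matplotlib 3.10.9.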

Results

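Expression in the hippocampal CA1 field, the output field of the hippocampal circuit, was measured in handled, unshocked mice on 4 arrays, with 1 array each at 1, 2, 4 and 6 hr. Per the labels they are the controls, matched by extraction time, of mice that received shocks. They show how far 4 single CA1 arrays differed when no shock was given. An effect of extraction time cannot be told apart from other differences between these samples or arrays. The median intensity was 204 at 1 hr, 173 at 2 hr, 204 at 4 hr and 198 at 6 hr. The share of values under the floor was 23.4% at 1 hr, 28.3% at 2 hr, 23.5% at 4 hr and 24.8% at 6 hr. The 3' to 5' signal ratio of the Actb control, a measure of RNA and labelling integrity, was 3.44 at 1 hr, 3.20 at 2 hr, 3.24 at 4 hr and 2.99 at 6 hr. That of the Gapdh control was 4.84 at 1 hr, 7.56 at 2 hr, 6.25 at 4 hr and 4.89 at 6 hr. The 3' control for 18S ribosomal RNA read 1383 at 1 hr, 1150.0 at 2 hr, 3325 at 4 hr and 3381 at 6 hr. Between 7 and 16 of 12488 values were identical in any pair of arrays, so each pair held different measurements. No value below has a replicate at its own time.

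No gene changed in a straight line with time past the threshold. Of 7453 probe sets, 0 passed limma's test after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.884. At an unadjusted p under 0.05 there were 382 probe sets, 214 higher and 168 lower with time, where 373 would be reached by chance. Ordinary least squares gave 0 after adjustment and 333 unadjusted, limma with an intensity-dependent robust prior gave 0 and 330, and the contrast of 4 and 6 hr against 1 and 2 hr gave 0 and 383. A total of 298 probe sets were in strictly rising order and 251 in strictly falling order, where 311 of each would arise by chance. On simulated data, with 200 probe sets changed and variances drawn whatever the mean level, the same test recovered 0% of 4-fold changes over 5 hr. Changes of that size were thus not detectable in that setting. The smaller spread of bright probe sets and other numbers of changed ones were not simulated.

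The genes with the smallest unadjusted p are given as values, since none passed. The probe set for Myog, a muscle transcription factor, read 86.9, 108, 232 and 425 at 1, 2, 4 and 6 hr, a slope of 0.47 ± 0.06 log2 units per hr (SE, limma adjusted p = 0.884). That for Hinfp, a regulator of histone H4 genes, went from 76.5 at 1 hr to 367 at 6 hr. Map3k12, a kinase of the neuronal stress response, lay at the floor at 1 hr and at 247 at 6 hr, at least 4.52-fold apart. Lin9, a subunit of a cell-cycle transcription complex, went from 72 to 205, and Sh3bp2, an adaptor protein, from 67.6 to 277. Tomm20, a mitochondrial import receptor, went from 99.7 to 370. The probe sets for Baz1b (61.0 to 311), Coro2b (68.7 to 219), Plekha1 (122 to 385) and Nop16 (at least 4.91-fold) were ordered likewise. The second probe set of Baz1b, a chromatin remodelling subunit, was in the same order within a smaller range, from 1994 at 1 hr to 2581 at 6 hr. The second probe sets of Coro2b, Plekha1 and Nop16 were not in time order.

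In the other direction, the probe set for Smarca5, an ATPase of chromatin remodelling complexes, read 251, 187 and 106 at 1, 2 and 4 hr and lay at the floor at 6 hr, a slope of -0.44 ± 0.06 log2 units per hr on the floored scale (SE, limma adjusted p = 0.884). A second Smarca5 probe set was not in time order and read 192 at 1 hr and 231 at 6 hr. The probe set for Traip, a ubiquitin ligase, went from 329 to 71.8 while another Traip probe set went from 88.5 to 274. Qsox1, a sulfhydryl oxidase, went from 224 to the floor, and Efl1, a GTPase of ribosome maturation, from 236 to the floor. Cog5, a Golgi complex subunit, went from 270.0 to 79.0, Ppp2r1b, a scaffold subunit of protein phosphatase 2A, from 246 to 75.4, and Rex1bd from 304 to 74.2. Gsg1 went from 382 to 59.6, and Cpne3, a calcium-dependent membrane-binding protein, from 741 to 191. Incenp, a chromosomal passenger protein, went from 366 to the floor, while its second probe set read 246 at 1 hr and 272 at 6 hr.

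**Figure D1:**
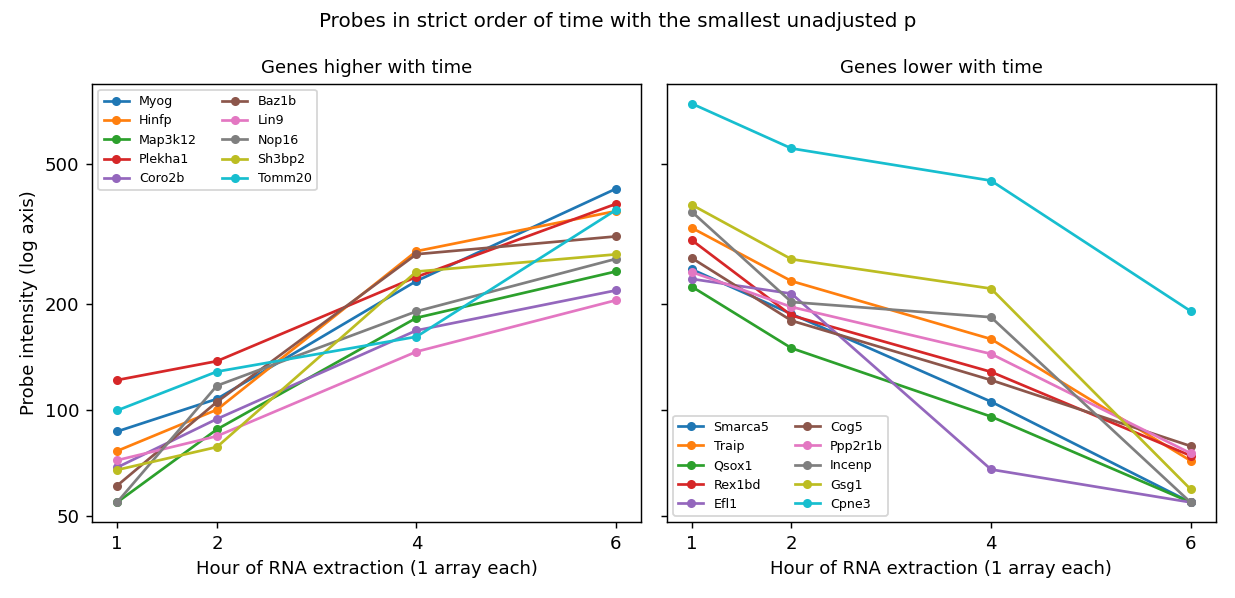
Probe intensity on a log axis against the hour of RNA extraction for the 10 genes with the smallest unadjusted p that were higher with time (left) and the 10 that were lower with time (right); each point is 1 array and points at 54.7 lie on the floor. Cpne3 lies highest, at 741 at 1 hr and 191 at 6 hr, and 0 of the 20 slopes passed the adjusted threshold.

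No pathway list passed the test of its slope, and heat shock and chaperone genes, whose products fold proteins, had the smallest adjusted p. Of their 20 tested members 16 had a slope below 0, with a median of -0.059 log2 units per hr (camera adjusted p = 0.0706, and adjusted p = 0.925 with an estimated correlation). Stip1, a co-chaperone, read 293, 140.0, 143 and 57.4 at 1, 2, 4 and 6 hr, and Pdia3, a protein disulfide isomerase, read 410, 551, 235 and 249. Hspb8 and Hspa9 had the largest differences the other way, at 0.24 and 0.18 log2 units. Members were most often highest on the 2 hr array, which held the maximum of 11 of the 20 and also had the highest Gapdh 3' to 5' ratio, 7.56. The Actb ratio of that array, 3.20, was not the highest (3.44 at 1 hr). Without the 2 hr array the camera adjusted p of this list was 0.484, and without the 1 hr array it was 0.0271 (adjusted p = 0.958 with an estimated correlation). The list lay 0.25 log2 units above the other arrays at 2 hr (percentile 99.7 of matched random lists), with a median difference of -0.19 at 6 hr (percentile 0.3). Cell-type markers shifted on these arrays too. At 2 hr inhibitory neurons were at percentile 98.6, CA1 neurons at 97.65 and choroid plexus at 0.6, and at 6 hr oligodendrocytes were at 0.01. For 4 and 6 hr against 1 and 2 hr the median difference of the heat shock list was -0.31 log2 units (camera adjusted p = 0.0127, and adjusted p = 0.868 with an estimated correlation). The 18S ribosomal RNA 3' control divided the arrays in the same way, at 1150.0 to 1383 at 1 and 2 hr and 3325 to 3381 at 4 and 6 hr. The 18S 5' control did not, at 440 at 1 hr, 133 at 2 hr, 289 at 4 hr and 572 at 6 hr. Over all alternatives the adjusted p of the list ran from 0.0127 to 0.925.

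Oxidative phosphorylation genes had 47 of 66 members with a slope below 0 and a median of -0.025 log2 units per hr (camera adjusted p = 0.105, and adjusted p = 0.925 with an estimated correlation). Atp5e, a subunit of ATP synthase, read 4056, 3182, 2612 and 2105 at 1, 2, 4 and 6 hr. Ndufab1, an acyl carrier protein of complex I, averaged 2565 ± 659 (SD, n = 4). Cox8c and Cox6b1 lay 0.30 and 0.43 log2 units higher at the later times. For 4 and 6 hr against 1 and 2 hr the median difference was -0.09 log2 units (camera adjusted p = 0.0384, and adjusted p = 0.868 with an estimated correlation). Without the 1 hr array the camera adjusted p was 0.0403 (adjusted p = 0.958 with an estimated correlation), and over all alternatives it ran from 0.0124 to 0.925. The lowest came with no filter on mean level, where the camera adjusted p with an estimated correlation was 0.728. The 18S 3' control divided the arrays along that contrast here too, while the 18S 5' control did not. On the 6 hr array the list's median difference was -0.076 (percentile 1.59). Ribosomal protein genes had 20 of 26 slopes below 0 and proteasome genes 22 of 37, and neither passed; the ribosomal list lay 0.14 log2 units above the other arrays at 1 hr (percentile 98.2). Rps13 read 134 at 4 hr against 473 to 676 on the other arrays, through a single probe set. Rps29 and Rpl32 lay 0.44 and 0.51 log2 units higher at the later times, and for Rpl22 the difference was -0.28 through the probe set used and at least 1.69 through its other one, which lay at the floor at 2 hr. Psmd12 and Psmd5 averaged 610 ± 198 and 1507 ± 429, and Psmd3 and Psmd9 averaged 584 ± 195 and 490 ± 126 (SD, n = 4). The difference of later from earlier times was -0.77 log2 units for Psmd12 and 0.65 for Psmd3.

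Genes that respond to neuronal activity or stress hormones were split in direction. Immediate early genes, which neurons induce within minutes of activity, had 11 of 24 slopes above 0 (median -0.016). Egr1 averaged 1877 ± 268 and Gadd45b 306 ± 60.8 (SD, n = 4), the latter with a second probe set of opposite sign. Egr2 read 370 at 4 hr against 125 to 142 on the other arrays. Fosl2 read 289 at 4 hr and lay at the floor at 2 hr. Glucocorticoid responsive genes had 11 of 20 slopes above 0, and their median on the 6 hr array lay 0.21 log2 units above the other arrays, at percentile 99.4 of matched random lists. Cell-type markers shifted on that array too, with oligodendrocytes at percentile 0.01, endothelial and mural cells at 1.62 and astrocytes at 98.2. Cdkn1a, a cell-cycle inhibitor, went from 260 at 1 hr to 76.5 at 6 hr, and Tsc22d3 ranged from the floor at 4 hr to 221 at 1 hr. Gjb6 and Hif3a lay 0.35 and 0.59 log2 units higher at the later times, with a difference of 0.02 for the second Gjb6 probe set. Of 17 circadian clock genes 12 had a slope above 0, and their median difference on the 1 hr array was -0.23 (percentile 0.73). Dbp, a clock output transcription factor, read 426, 342, 546 and 672 at 1, 2, 4 and 6 hr, and Arntl, a core activator of the clock, read 601, 732, 525 and 496. Rora went from 67.6 to 252 and Per3 from 406 to 175. Of 13 NF-kB pathway genes 6 had a slope above 0. Tnfrsf1a and Tnfrsf1b, both receptors for TNF, lay 0.96 and 0.62 log2 units higher at the later times, and the differences were -0.24 for Vcam1 and -0.19 for Birc2, whose second probe set, at the floor at 2 hr, differed by at least 1.07 the other way. The median slope was below 0 and the mean slope above 0 for immediate early and NF-kB pathway genes, and for the latter camera's direction was that of the mean. None of these 4 lists passed camera's test, with adjusted p between 0.575 and 0.935.

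Genes of synapses and chromatin did not pass either. Ionotropic glutamate receptors had 7 of 9 slopes above 0 and lay 0.41 log2 units above the other arrays at 6 hr (percentile 98.9). Grid1 read 490 at 4 hr and 66.7 at 2 hr, and Grin2a was at the floor at 2 hr and at 208 to 269 otherwise. Grin2b was at the floor at 6 hr, and Gria3 read 195 at 4 hr against 357 to 491 otherwise. GABA-A receptors had 3 of 3 slopes above 0. Those of Gabrg3 and Gabrb1, 0.012 ± 0.093 and 0.015 ± 0.067 log2 units per hr (SE), were smaller than their SE. Gabra2 read 1228 at 6 hr against 279 to 570 on the other arrays, while Gabrb1 averaged 5387 ± 543 and Gabrg3 136 ± 33.1 (SD, n = 4). Synaptic vesicle genes had 13 of 21 slopes below 0, and the list lay 0.25 log2 units above the other arrays at 1 hr (percentile 99.9), where 11 of 21 members were highest. Rab3a, a vesicle GTPase, read 215 at 1 hr and 621 to 757 later, whereas Rab3b went from 436 to 133. Syt3 read 367 at 2 hr against 777 to 909 otherwise, while its second probe set was not lowest at 2 hr (309.5 against 191 to 362), and Vamp1 went from 206 to the floor. Chromatin deacetylases and acetyltransferases had 10 of 15 slopes above 0, and 10 of the 15 were lowest on the 1 hr array, where the median difference was -0.33 (percentile 0.2). Blood markers were at percentile 98.4 on the 1 hr array. It also had the highest Actb 3' to 5' ratio (3.44) but the lowest Gapdh ratio (4.84). Hdac1 went from 93.2 to 364, Hdac2 averaged 1135 ± 318 and Ncoa3 187 ± 66.9 (SD, n = 4). The adjusted p of these 4 lists under camera lay between 0.454 and 0.662, where ribosomal proteins also had 0.454 and the proteasome 0.662.

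**Figure D2:**
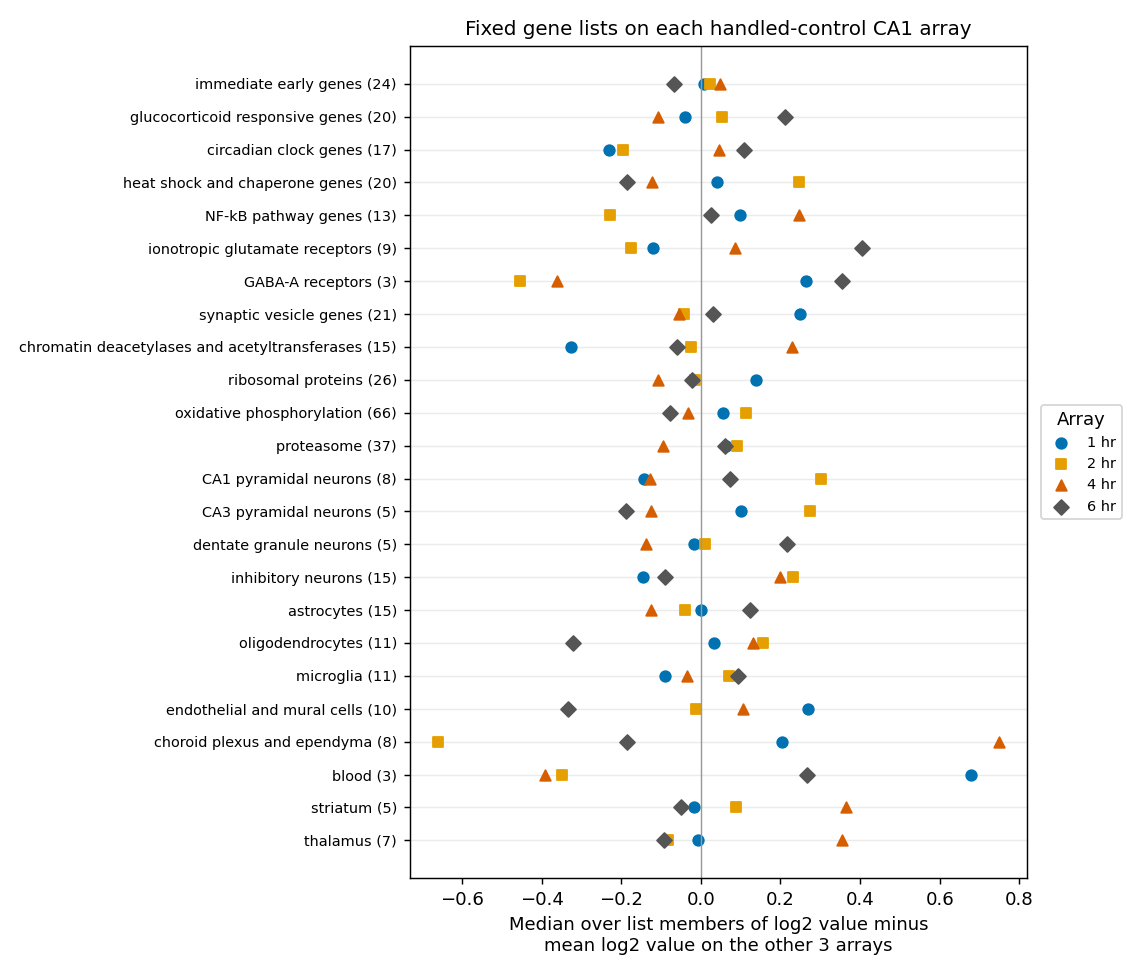
Median over the tested members of each fixed gene list (number in brackets) of the log2 value on 1 array minus the mean log2 value on the other 3, with 1 symbol per array; there are no error bars because each time has 1 array. The choroid plexus and ependyma list spans the widest range, from -0.66 at 2 hr to 0.75 at 4 hr.

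Markers of the cell types that a CA1 dissection can hold were compared in the same way, and no list passed. CA1 pyramidal neuron markers had 3 of 8 slopes above 0 and lay 0.30 log2 units above the other arrays at 2 hr (percentile 97.65). Dcn averaged 3067 ± 743, Lefty1 773 ± 196, Pou3f1 513 ± 84.5 and Man1a 978 ± 189 (SD, n = 4), the last with a second probe set of opposite sign. CA3 pyramidal neuron markers had 5 of 5 slopes below 0. Nnat read 2015 at 1 hr and 744 to 982 later, Socs2 averaged 740 ± 155 and Bok 878 ± 197 (SD, n = 4). Dentate granule neuron markers had 4 of 5 slopes above 0, with Il16 at 89.2 at 2 hr and 199 to 251 otherwise, Lct at 392 ± 71.0, Marcks at 1376 ± 376 and Penk at 1712 ± 185 (SD, n = 4). The difference of later from earlier times was -0.05 log2 units for this Penk probe set and 1.07 for its second one. Inhibitory neuron markers had 7 of 15 slopes above 0 and lay 0.23 log2 units above the other arrays at 2 hr (percentile 98.6). The 2 hr array also had the highest Gapdh 3' to 5' ratio (7.56), the lowest median intensity (173) and the most values under the floor (28.3%), and choroid plexus markers were at percentile 0.6 there. Its Actb ratio (3.20) was not the highest (3.44 at 1 hr). Gad1, the GABA-synthesising enzyme, averaged 4052 ± 508, Lhx6 460 ± 74.4, Calb2 288 ± 122 and Dlx2 130 ± 31.1 (SD, n = 4). Astrocyte markers had 10 of 15 slopes above 0. Slc1a2, the main glial glutamate transporter, read 218, 330, 451 and 580 in time order, Gja1 averaged 5679 ± 736 and Ndrg2 3233 ± 423 (SD, n = 4). Glul read 1450 at 4 hr against 758 to 896 otherwise. Its second probe set was also highest at 4 hr, at 515 against 449 and 495 at 1 and 2 hr, but read 127 at 6 hr. The difference of later from earlier times was 0.43 log2 units for the former and -0.89 for the latter. Microglial markers had 7 of 11 slopes above 0, with Csf1r at 1607 ± 372, Cd14 at 525 ± 69.9, Cd68 at 329 ± 80.4 and Tyrobp at 668 ± 51.1 (SD, n = 4).

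Oligodendrocyte markers, genes of the myelin-forming cells, had 8 of 11 slopes below 0 with a median of -0.066 log2 units per hr (camera adjusted p = 0.165, and adjusted p = 0.925 with an estimated correlation). On the 6 hr array 7 of the 11 were at their lowest, and the median difference of the list was -0.32 log2 units, at percentile 0.01 of matched random lists. On the same array the median difference of endothelial and mural markers was -0.33 (percentile 1.62) and that of astrocyte markers was 0.12 (percentile 98.2). Cldn11, a tight-junction protein of myelin, read 665, 768, 549 and 446 in time order, and Mog, a myelin surface protein, read 619, 661, 542 and 405. Sox10 and Mag lay 0.25 and 0.23 log2 units higher at the later times. Without the 6 hr array the adjusted p was 0.956, without the 1 hr array it was 0.0271 (adjusted p = 0.958 with an estimated correlation), and over all alternatives it ran from 0.0271 to 0.956.

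Endothelial and mural markers had 6 of 10 slopes below 0 (camera adjusted p = 0.582). Over all probe sets 0 of them passed limma's test, and 2 passed when adjusted over the list alone (smallest adjusted p = 0.047). These 2 are both genes of smooth muscle and went opposite ways: Tagln was at the floor at 1 hr and at 284 at 6 hr, and Acta2 read 201 at 1 hr and was at the floor at 6 hr. Cldn5, a tight-junction protein of brain endothelium, read 621, 639, 394 and 318 in time order, and Slc2a1 read 77.1 at 1 hr and 140.0 to 327 later. In no other list did a member pass when adjusted over the list alone. Blood markers had 1 of 3 slopes above 0. Hba-a1 averaged 2846 ± 877, Hbb-b2 450 ± 127 and Slc4a1 135 ± 59.3 (SD, n = 4), and the list lay 0.68 log2 units above the other arrays at 1 hr (percentile 98.4). Globin genes have near-identical copies whose signals cannot be told apart here. Striatal markers had 3 of 5 slopes above 0, with Drd2 at 221 ± 45.3, Tac1 at 227 ± 47.8, Pde1b at 707 ± 197 and Ptpn5 at 988 ± 181 (SD, n = 4). Thalamic markers had 4 of 7 slopes above 0. Ramp3 read 307 at 1 hr and 118 at 6 hr, Zic1 was at the floor at 1 hr and at 231 at 6 hr, and Tcf7l2 averaged 559 ± 190 (SD, n = 4). The median and mean slopes differed in sign for CA1 neurons, inhibitory neurons, blood and striatum. The camera adjusted p of the marker lists not given singly ran from 0.454 to 0.935.

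Among the genes named for a single array, Ttr, transthyretin, a secreted product of the choroid plexus, lay farthest from the nearest other array, at 16.4-fold. Its intensity was 140 at 1 hr, 140 at 2 hr, 3217 at 4 hr and 196 at 6 hr, so the 4 hr array lay 20.5-fold above the mean of the others, a mean taken on the log2 scale here and below. The choroid plexus and ependyma list lay 0.75 log2 units above the other arrays at 4 hr, at percentile 99.95 of matched random lists, and its median difference at 2 hr was -0.66, at percentile 0.6. Without Ttr the median at 4 hr was 0.64, and with the 1 hr array also left out it was 0.36, at percentile 84.1. Igf2 and Igfbp2, named after their values were seen, were 1.82-fold and 1.92-fold above the other arrays at 4 hr. Kl and Aqp1, of the same list, were not highest there: Kl read 370.0 at 2 hr and 266 at 4 hr, and Aqp1 317 at 1 hr and 118 at 4 hr. Over time the list had 7 of 8 slopes above 0 and did not pass (camera adjusted p = 0.935).

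**Figure D3:**
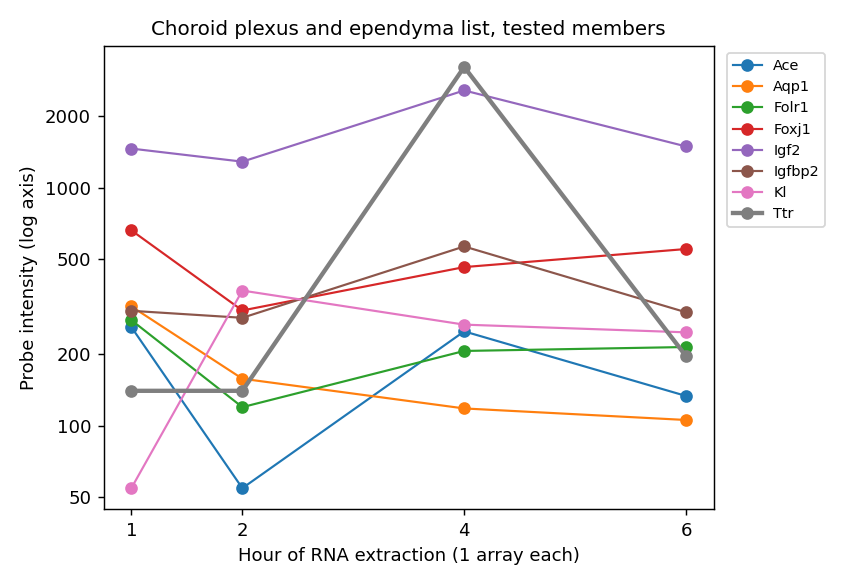
Probe intensity on a log axis against the hour of RNA extraction for the 8 tested members of the choroid plexus and ependyma list, with 1 array per point and Ttr as the thick line. Ttr is at 3217 on the 4 hr array and between 140 and 196 on the other 3, and Igf2 and Igfbp2 are also highest there; the Ace value at 2 hr lies on the floor of 54.7.

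Across all tested probe sets, 101 lay at least 2-fold above the other 3 arrays on a single array and 475 lay at least 2-fold below. With no filter on mean level there were 670 above and 533 below, and with the floor at the 40th percentile 140 above and 133 below. The 1 hr array had 35 above and 140 below, the 2 hr array 14 and 140, the 4 hr array 24 and 88, and the 6 hr array 28 and 107. On the 1 hr array the highest were Arnt2, a bHLH-PAS transcription factor (4.28-fold above the mean of the others), the ion channel P2rx6 (3.95-fold), Gpr3 (3.98-fold), Emp3 (3.70-fold, with a second probe set that was not highest there) and Proc (at least 3.71-fold). The lowest there were Meg3, an imprinted long non-coding RNA (87.8 against 940 to 3416), Atf6b (6.67-fold), Acsf3 (6.23-fold), Snapc3 (5.60-fold) and Kl (5.29-fold). The second probe sets of Meg3 and Atf6b were also lowest at 1 hr, the latter at 309.7 against 399 to 426. On the 2 hr array the acetyltransferase gene Kat2a (4.87-fold), Cherp (3.93-fold), Nbl1 (4.14-fold), Nav1 (2.78-fold above the nearest array) and 1 of 4 Gstm5 probe sets (4.26-fold) were highest. Tmem129 (at least 7.39-fold), H2-M10.1 (6.84-fold), Pip4k2c (at least 5.84-fold), Fmnl1 (at least 5.51-fold) and Gsta2 (at least 4.82-fold) were lowest there. The second probe sets of Tmem129, H2-M10.1, Pip4k2c and Fmnl1 were not 2-fold lower there. That of Pip4k2c was highest there, at 1031 against 630 to 726, while those of H2-M10.1 and Fmnl1 were lowest there.

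On the 4 hr array Gpn3 (at least 5.03-fold), Idnk (4.12-fold), Pnliprp2 (at least 3.67-fold) and Slc5a11, a myo-inositol transporter (3.22-fold), followed Ttr. Spin1 (6.69-fold), Srpr (at least 5.72-fold), Zfp213 (at least 5.17-fold), Mphosph10 (at least 4.76-fold) and Ebp, an enzyme of sterol synthesis (4.49-fold), were lowest there. Second probe sets of Spin1 and Srpr were not 2-fold lower there. That of Spin1 was lowest there, and that of Srpr was highest, at 1672 against 1336 to 1623. On the 6 hr array the actin-binding protein gene Pfn1 (at least 6.54-fold), Slc6a2, the noradrenaline transporter (4.52-fold), Pklr (4.35-fold), Ebi3 (3.51-fold) and Gtf2f2 (2.97-fold) were highest. H2bc22 (at least 8.20-fold), Rsl1d1 (5.79-fold), Ctse (at least 5.63-fold), Tuft1 (at least 4.88-fold) and Ifna5 (4.86-fold) were lowest. Second probe sets of H2bc22, Rsl1d1 and Ctse were not 2-fold lower there. That of H2bc22 was highest there, at 233 against 130 to 206, and that of Ctse was lowest.

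The spread between the 4 arrays was small for bright probe sets and large for dim ones. The median SD of a probe set was 0.29 log2 units, and 74.7% of probe sets had all 4 values within 2-fold. Among the 1491 dimmest probe sets, with mean intensities from 114 to 199.9, the median SD was 0.58. Among the 1491 brightest, with means of 1232 or more, it was 0.18. Across probe sets, which are not independent replicates, Pearson's r between arrays ran from 0.92 to 0.94, and between 638 and 752 probe sets were 2-fold or more apart in a pair of arrays. Of the 101 probe sets that stood 2-fold above on 1 array, 78 were among these dimmest, and of the 475 that stood below, 316 were.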

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

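The tests of explanations in this part were chosen after the results were seen. The 4 handled controls were treated as 1 set of 4, and 128 measures (array measures, list medians and named list members) were checked for a single array far from the other 3 by Dixon's ratio at its critical value for 4 values. Of these, 6 stood apart. Chance gives about 1 in 20 sets of values, a rate that does not hold for the list members, which were named for large differences between later and earlier arrays.

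Transthyretin (Ttr) read 3217 on the 4 hr array and 140 to 196 on the others. A candidate explanation is choroid plexus tissue carried over with that sample: the 7 other tested members of the choroid plexus and ependyma list, fixed beforehand, had a median difference of 0.64 log2 units on that array, at percentile 99.0 of matched random lists, but 0.36 (percentile 84.1) without the 1 hr array, 0.42 (percentile 94.3) without the 2 hr array and 0.90 (percentile 99.8) without the 6 hr array, so carry-over stays open. Of the 7, 5 were above the mean of the other arrays and 2, Igf2 and Igfbp2, were above all of them. Kl (266), Folr1 (206), Ace (249), Foxj1 (464) and Aqp1 (118) were not highest there. All 17 probe sets of the list's genes on the array, with Ttr, include 9 below the filter. Of the 17, 8 were highest at 4 hr, 6 at 1 hr, 2 at 2 hr and 1 at 6 hr. Below the filter, Slc4a5 (92.9 against 4.2 to 11.6), F5 (178.8 against 13.2 to 65.7) and Calml4 (268.6 against 20.3 to 165) were among those highest at 4 hr. Their lower values reach under the floor. Cldn2 and the other probe sets of Ace and Aqp1, also below the filter, were not highest there. The overall scale of the deposited 4 hr values differed little: their median lay 0.034 log2 units above the mean of the 4 array medians. Quantile normalization or a common median therefore could not remove a difference as large as that of Ttr. It stayed at least 4.31 log2 units under both, which is no separate evidence. A change of Ttr within CA1 cells at that hour was not tested and stays open, because there is 1 array at 4 hr.

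The other flagged values are given without explanation. Egr2 read 369.5 at 4 hr against 125 to 142 on the other arrays. Kat2a read 585 at 2 hr against 110 to 137. Lefty1 read 1066 at 6 hr against 651 to 699. Dlx2 read 83.1 at 4 hr against 142 to 149. The median deviation of the proteasome list from the mean of the 4 arrays was -0.072 log2 units at 4 hr against 0.046 to 0.069 on the others.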

How the results depend on the processing

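The count of 0 probe sets with a trend was kept in all 15 alternatives, with a smallest adjusted p from 0.352 to 0.997. The count at an unadjusted p under 0.05, 382, was 782 with no filter and 229 with a filter at the 60th percentile, where other numbers of probe sets were tested. Of the 20 named slopes 0 passed in 259 alternative values; their signs say nothing of stability, since the genes were chosen for strict time order. The order of the arrays was tested as well, a check chosen after the result was seen: 16 of the 24 orders gave at least the 382 probe sets at an unadjusted p under 0.05, with 458 in the highest other order, so chance cannot be excluded. No paired analysis was possible because each time has 1 array and all carry the same number. The count of probe sets beyond all other arrays, 576, was 273 with the floor at the 40th percentile, 1203 with no filter, 83 with a filter at the 60th percentile and 1807 at 1.5-fold. Its part above, 101, was 670 with no filter, 12 at the 60th percentile, 565 at 1.5-fold and 183 to 231 with 1 array left out, where fewer arrays need be exceeded. Its part below, 475, was 133 with the floor at the 40th percentile, 71 at the 60th percentile and 1242 at 1.5-fold. The median SD was 0.23 at the 60th percentile and 0.25 to 0.28 with 1 array left out. The count of lists that changed with time, 0, was 1 with no filter and 1 with the filter at the 60th percentile (oxidative phosphorylation in both), 2 for 4 and 6 hr against 1 and 2 hr (heat shock and oxidative phosphorylation), and 0 to 3 with 1 array left out, the 3 (heat shock, oxidative phosphorylation, oligodendrocytes) without the 1 hr array. The cause was not tested. Without the 4 hr array, a fit looked at again after Ttr was seen, 0 lists passed. The count was 0 with an estimated correlation, also under each of these settings, fits added after the data were seen. With so few residual degrees of freedom that form can hardly pass any list, so this count decides nothing. For oxidative phosphorylation the unadjusted camera p rose from 0.0088 to 0.09998, though the estimated correlation, 0.00505, was below the preset 0.01.

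The sign of the median slope of 14 of the 24 lists, none of which passed, turned under some setting. In log2 units per hr, quantile normalization gave 0.0032 for blood and -0.0048 for thalamus, a common median gave -0.0033 for microglia and -0.0027 for thalamus, and the floor at the 40th percentile gave 0.0029 for inhibitory neurons. No filter gave -0.033 for GABA-A receptors and 0.0026 for blood, and the filter at the 60th percentile gave 0.015 for NF-kB and -0.019 for striatum. Per log2 of hours the medians were 0.013 for NF-kB, 0.019 for inhibitory neurons and -0.0033 for thalamus. All probe sets of a gene gave 0.038 for NF-kB and 0.0029 for inhibitory neurons. For 4 and 6 hr against 1 and 2 hr, the median differences were 0.077 for NF-kB, -0.0057 for GABA-A receptors, 0.0025 for inhibitory neurons, 0.033 for blood and -0.053 for striatum. With 1 array left out the medians ran from -0.039 to 0.018 for astrocytes, -0.075 to 0.19 for blood, -0.075 to 0.017 for CA1 neurons, -0.021 to 0.30 for choroid plexus, -0.014 to 0.074 for chromatin enzymes, -0.17 to 0.15 for GABA-A receptors, -0.030 to 0.050 for glucocorticoid genes, -0.022 to 0.039 for immediate early genes, -0.052 to 0.047 for inhibitory neurons, -0.024 to 0.026 for microglia, -0.013 to 0.049 for NF-kB, -0.035 to 0.0064 for the proteasome, -0.033 to 0.025 for striatum and -0.028 to 0.10 for thalamus. Of 244 alternative values of single-array gaps 29 moved by more than the spread of the other arrays.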

Other observations

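The tests of explanations and the percentiles of list spread in this part were chosen after the results were seen. The fixed lists differed in how far their members varied between the 4 handled controls, set against random lists of the same mean level. Ribosomal protein genes varied least, with a median SD of 0.13 log2 units at percentile 0.35. Synaptic vesicle genes, at 0.34, were at percentile 99.8, ionotropic glutamate receptors, at 0.61, at percentile 99.1, choroid plexus and ependyma genes, at 0.61, at percentile 98.2, CA1 pyramidal neuron markers, at 0.31, at percentile 97.8, and thalamic markers, at 0.67, at percentile 97.52. Of 96 list medians on single arrays 17 lay in the outer 2.5% at either end, where 4.8 would be expected if genes varied independently.

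Meg3 was in rising time order through both of its probe sets, at 87.8, 940, 2724 and 3416 and at 767, 1119, 1475 and 2003 (slopes 0.95 ± 0.24 and 0.26 ± 0.06 log2 units per hr, SE, limma adjusted p = 0.884 for both). A fault of a single probe set is argued against for the order, because the second one spanned 1.38 log2 units in the same order. The sizes differ, 38.9-fold and 2.61-fold between 6 and 1 hr, so a fault that enlarges the first is not excluded. A change of RNA integrity with time stays open: 0 of the Actb and Gapdh 3' to 5' ratios were in strict time order, but the Actb ratio was highest at 1 hr (3.44) and lowest at 6 hr (2.99), and each ratio has 1 value per time. An effect of extraction time on Meg3 stays a hypothesis, since the trend did not pass and other differences between samples or arrays are confounded with time.

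Probe sets below all other arrays outnumbered those above by 4.70 to 1. Without the filter on mean level that ratio was 0.796, so the filter, which removes probe sets with 3 dim values and 1 bright one, may account for the excess. From mean levels, whether signal near the floor adds to it cannot be told: 10.1% of the probe sets below and 7.92% of those above lay in the upper 60% by mean level. With the floor at the 40th percentile there were 140 above and 133 below both with and without the filter, so that setting does not separate floor from filter. Other settings do. Without the filter there were 1265 above and 1263 below with the floor at the 10th percentile, and 670 and 533 at the 25th. With the filter at the 60th percentile there were 12 above and 70, 71 and 76 below with the floor at the 10th, 25th and 40th percentile. These counts argue against the floor as the source of the excess on its own. No biological explanation was tested.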
